A study of Mus musculus with 2 samples.

How the data were processed

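Total RNA from splenic CD4+ alpha beta T cells of wildtype and LatY136F mice was compared on 2 two-colour arrays, each holding both RNAs. LatY136F carries a tyrosine-to-phenylalanine substitution in Lat, the membrane adaptor that couples the T cell receptor to downstream signalling. Per the labels, T cells were selected from spleen with anti-CD4 magnetic beads and a cell sorter, and the arrays form a dye-reversal pair: array 1 (+ polarity) had wildtype RNA in channel 1 and LatY136F RNA in channel 2, and array 2 (- polarity) had them the other way round. The labels do not say whether the arrays used separate RNA extracts or how many mice gave RNA. The pair was therefore counted as 1 biological comparison, no test of the conditions was made, and the difference between the arrays gives no spread between animals and may be technical only.

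The deposited table holds 1 log ratio per probe and array for 8014 probes, with no missing value. The scanner signals were not analysed here, so how bright a probe was, and hence how precise its ratio is, is unknown; the number of arrays limits the precision. The deposited values were read as log10 ratios. The base is not given in the sources used here; the highest value of array 1 is exactly 2, which reads as a 100-fold cap on a log10 scale, so log10 is likely and not certain. Background correction, normalization and filters are not given in the sources used here. The medians of the deposited log10 ratios were -0.0033 on array 1 and 0.0070 on array 2. A value of exactly 0 stood at 57 probes of array 1 and 60 of array 2, 28 of them at the same probe.

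The direction of the ratio is not stated either. Values were assumed to be channel 2 over channel 1. The labels name the channel 1 RNA first on both arrays, so their order does not speak for this reading. Array 2 was multiplied by -1, because the deposited columns had a Pearson correlation of -0.21 over all probes (Spearman rho -0.06). This was taken to mean that they had not been turned alike. Every ratio below is LatY136F over wildtype under this assumption, called the likely direction. If the opposite reading holds, every "higher" becomes "lower". Published background describes LatY136F CD4+ T cells as strongly polarised to the T helper 2 (Th2) type, so the sign of the Th2 genes serves as a check of the reading and is not independent evidence.

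Log10 ratios were multiplied by 3.32 to give log2 ratios and each array was centred on its median. The platform annotation gave 1 gene symbol to 4654 probes, several to 73 and none to 3287. Probes with several symbols or none were not named. Of the 4654, 4640 had a gene identifier in the RefSeq gene table (GRCm38.p6), and no symbol needed an update. Probes of a gene were averaged, which left 4331 genes, 294 of them with more than 1 probe. Probes of near-identical families (immunoglobulin, killer lectin-like and Lilr receptor, lysozyme and globin genes) can share target RNA, so their assignment is uncertain.

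Before the data were examined, a gene was called higher or lower when its log2 ratio was at least 1 or at most -1 on both arrays. The following were fixed at the same time: 33 gene lists, the alternatives, and the genes to name. Named genes were Lat, Il4 and Gata3; the 12 genes furthest from 0 on each side among those called; and up to 4 members per list among those at least 1.5-fold apart the same way on both arrays, or 2 members where none was. Batf, Irf4, Il10, Maf, Stat6, Ifng, Il2ra, Cd44, Cd4, Cd3e, Cd8a, Cd79a, Itgam, Ctss, Marco and Msr1 are list members outside this rule, named after their values were seen. A list's median log2 ratio was placed among the medians of 10000 random lists of as many measured genes. These could not be matched on signal, and the percentile describes these arrays only. Of 730 listed genes, 444 were measured; 31 lists had at least 3 measured genes and entered the counts. A list was set apart when its median lay outside the central 95% of random lists. Chance would put about 0.78 lists on each side if list members behaved as randomly drawn genes. Members of a list may vary together, so more lists could pass, which was not tested.

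The calling rule and the list percentiles were tested on simulated data: errors drawn from the real differences between the arrays were added to 4331 genes, 200 of them changed. For LatY136F against wildtype, 92% of genes with a true 3-fold change were called, 86% with a 4-fold change, 18% with a 2-fold change and 2% with a 1.5-fold change. Each rate rests on 50 genes of 1 simulated draw, so the 3-fold and 4-fold rates cannot be ranked. Of 4131 unchanged genes, 18 were called. Errors were drawn separately for each array from 1 pool shared by all genes. Genes that are noisy on both arrays, and dye errors of opposite sign on the turned arrays, were therefore not imitated. The real arrays held 75 genes at least 2-fold apart in opposite directions, so false calls may be more frequent than simulated. A simulated list moved by 0.5 on the log2 scale lay above all random lists, and 6.2% of unmoved lists lay outside the central 95%. limma's moderated test on the 2 arrays as if they were replicates, with Benjamini-Hochberg adjustment, measures only the spread between these arrays, which may be technical, and recovered none of the 200 genes and called no unchanged gene. Other alternatives were no centring, scaling the arrays to the same spread, each array alone, thresholds of 1.5-fold and 3-fold, a threshold on the mean, other ways of joining probes and the turned sign. Reading the values as log2 and leaving out probes at exactly 0 were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.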

Results

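RNA from CD4+ alpha beta T cells of LatY136F and wildtype mouse spleens was compared directly on 2 arrays with the dyes reversed. The comparison asks which transcripts differ between T cells carrying the Lat substitution and wildtype T cells. Values are mean log2 ratios of LatY136F over wildtype, in the likely direction of the ratio; ± gives 0.5 times the difference between the 2 arrays, which may be technical error only. There is 1 biological comparison, so no p-value is attached to any gene.

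Of 4331 genes, 182 were at least 2-fold higher in LatY136F cells on both arrays and 42 were at least 2-fold lower. Of these 224 genes 81.3% were higher. At least 4-fold differences on both arrays were seen for 44 higher and 8 lower genes, and at least 8-fold differences for 18 higher genes and 1 lower gene. In comparison, 75 genes were at least 2-fold apart in opposite directions on the 2 arrays, and for 176 genes (4.06%) 0.5 times the difference between the arrays was at least 1 on the log2 scale. When the values of array 2 were shuffled over the genes 1000 times, 32.2 genes on average were called higher (49 at most) and 5.01 lower (14 at most). Across genes, which are not independent replicates, the arrays correlated with a Pearson r of 0.33 and a Spearman rho of 0.16. The same sign on both was seen for 55.8% of genes. Array 2 was turned because the deposited columns correlated negatively, a choice that itself favours a positive r. Over all genes the median of 0.5 times the difference between the arrays was 0.15.

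**Figure D1:**
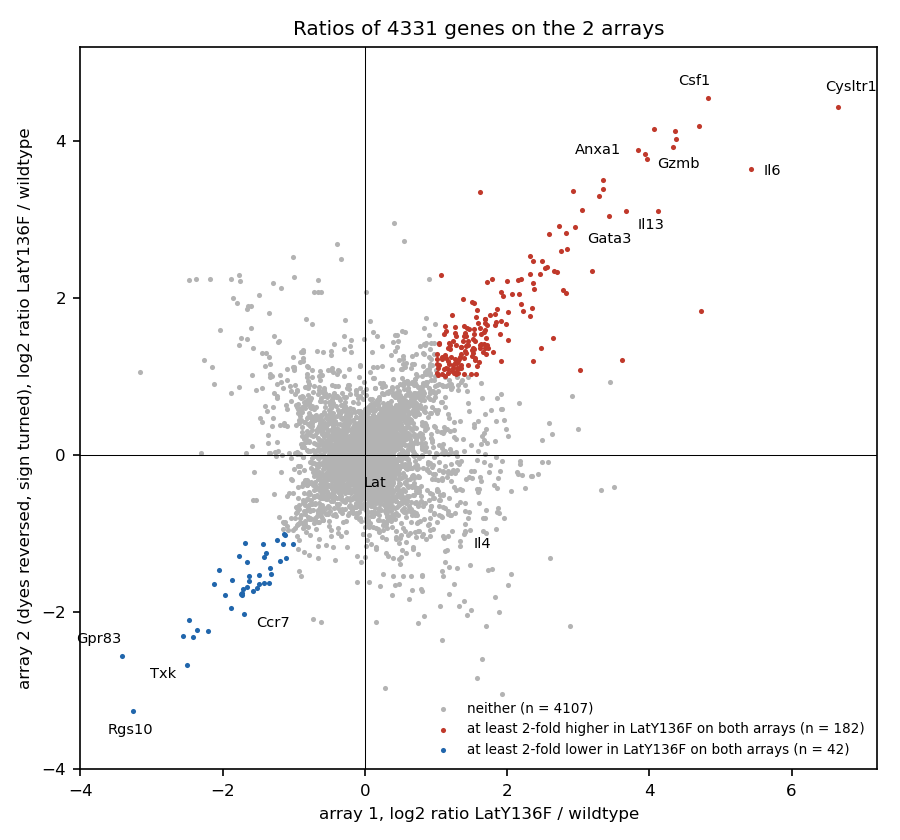
Log2 ratio of LatY136F over wildtype on array 1 (x axis) against array 2 with its sign turned (y axis), 1 point per gene for 4331 genes. The 182 genes at least 2-fold higher on both arrays (red) and the 42 lower (blue) lie along the diagonal, while most other genes (grey) gather around 0 and 75 lie beyond 2-fold in opposite directions; Il4 is one whose arrays disagree in sign.

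The strongest ratio belonged to Cysltr1, a receptor for cysteinyl leukotrienes, at 5.54 ± 1.11. Its value on array 1 was at the 100-fold limit of the table, so the ratio there is a lower bound, and array 2 gave 4.43. Csf1, the growth factor of macrophages, stood at 4.69 ± 0.14 (25.7-fold), and the cytokine Il6 at 4.54 ± 0.89 (23.3-fold). The chemokine Ccl8 was 21.7-fold higher, Slpi, a secreted protease inhibitor, 19.0-fold, and the early response gene Ier3 18.4-fold. The integrin gene Itgb2l was 17.5-fold higher, the protease gene Bace2 17.3-fold and the cytotoxic protease Gzmb 14.8-fold. The phosphatase Ptpn13 was 14.7-fold higher, Anxa1 14.5-fold and the decoy interleukin-1 receptor Il1r2 12.3-fold. Il1r2 is also on the neutrophil list, and monocyte and neutrophil markers were higher too. Whether T cells or other cells gave these ratios was not tested.

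At the other end, Rgs10, a regulator of G protein signalling, had the lowest ratio of all genes, at -3.26 on each array (9.59-fold lower). The G protein-coupled receptor gene Gpr83 was 7.92-fold lower, at -2.99 ± 0.43. Txk, a kinase of T cells, stood at -2.59 ± 0.09 and the kinase gene Srpk3 was 5.39-fold lower. The immunoglobulin genes Igha and Ighm were 5.18-fold and 3.76-fold lower, and Cd79b, part of the B cell receptor, 4.89-fold. The 2 Ighm probes differed, at -2.85 and -0.98. Usp28 was 4.91-fold lower, Cd8b1, a chain of the CD8 co-receptor, 4.67-fold, and Pgap1 3.69-fold. The costimulatory receptor Cd27 (3.66-fold lower) and Ccr7, the receptor that guides T cells into lymph nodes (3.64-fold lower), completed this set.

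**Figure D2:**
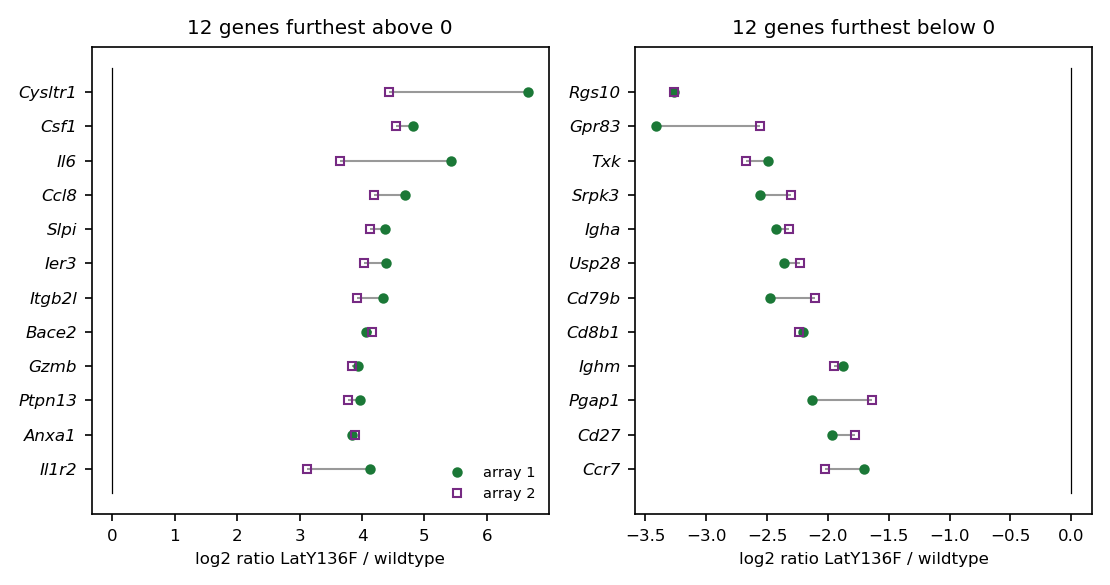
Log2 ratio of LatY136F over wildtype (x axes) on array 1 (filled circles) and array 2 with dyes reversed (open squares) for the 12 genes furthest above 0 (left) and furthest below 0 (right) among genes called on both arrays; grey bars join the arrays and the vertical lines mark 0. The arrays lie close together for most genes, with the widest gap for Cysltr1 (6.65 and 4.43).

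Genes of the Th2 programme were higher in LatY136F cells. Of 20 measured, 7 were at least 2-fold higher on both arrays and none lower, and the list's median of 0.83 exceeded all 10000 random lists. Il13, a Th2 effector cytokine, was 10.5-fold higher (3.39 ± 0.27), Gata3, the Th2 master transcription factor, 7.63-fold (2.93 ± 0.02) and Il17rb, the receptor for interleukin-25, 4.56-fold (2.19 ± 0.04). Il6 and, named after their values were seen, Batf (2.01), Irf4 (1.22) and Il10 (1.22) made up the rest. Il4, the defining Th2 cytokine, gave 1.41 on array 1 and -0.97 on array 2 and so has no direction here. Of the 20 genes, 14 had the same sign on both arrays, at the 89.8th percentile of random lists. Maf, a transcription factor that acts on Il4, stood at -0.39 and Stat6 at -0.15. Because this list served to check the sign of the ratio, its direction is not independent evidence. Monocyte and macrophage markers were higher too (median 1.20) and B cell markers lower (median -0.70).

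The Th1 list had a median of 0.12, at the 86.6th percentile of random lists. Il12rb1, a subunit of the interleukin-12 receptor, was 7.12-fold higher and the homeobox factor Hlx 2.82-fold. The Th1 chemokine receptor Cxcr3 stood at -0.86 ± 0.21, below the 2-fold threshold, and Ifng at 0.18. The Th17 and follicular helper list (9 measured) had a median of -0.02, at the 42.6th percentile. Its member Ahr, a ligand-activated transcription factor, was 2.35-fold higher, while Ccr6 stood at -1.05 ± 0.19. Of 12 genes of the regulatory T cell list, 5 were higher, among them the ectonucleotidase Entpd1 (3.78-fold) and the costimulatory receptors Tnfrsf18 (3.41-fold) and Tnfrsf4 (1.58 ± 0.05 on the log2 scale), and 1, Gpr83, was lower. The list's median of 0.66 exceeded all random lists. Its member Foxp3 was not measured, so the list does not test for regulatory T cells. The members named as higher are also found on activated T cells, and Il2ra stood at -0.29 with opposite signs on the arrays.

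Activation and memory genes were higher and naive T cell genes lower. Of 30 activation and memory genes, 11 were at least 2-fold higher and none lower (median 0.77, above all random lists). They included Anxa1, the galectins Lgals3 (8.52-fold) and Lgals1 (5.39-fold) and the membrane-binding protein Anxa2 (5.45-fold). Cd44, a common memory marker, stood at 0.45 ± 0.27. Of 15 genes of naive cells and lymph node homing, 3 (Txk, Cd27 and Ccr7) were at least 2-fold lower and none higher, and the median of -0.63 lay below all random lists. Itga6, an integrin subunit, stood at -1.21 ± 0.28. Higher monocyte markers and lower B cell markers stood beside these groups as well.

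None of 28 measured genes of the T cell receptor complex and its proximal signalling was 2-fold apart, and the median was -0.02 (39.9th percentile; -0.09 on array 1 alone and 0.11 on array 2 alone). Lat itself stood at -0.17 ± 0.004; the mutation substitutes 1 amino acid, so its transcript level does not check the genotype. Cd4 stood at -0.17 and Cd3e at -0.01. The receptor Cd5, a negative regulator of T cell receptor signalling, was at 0.81 ± 0.11, the diacylglycerol kinase Dgka at -0.80 ± 0.12 and Lcp2, the adaptor SLP-76, at 0.71 ± 0.05. Of 29 immediate early and receptor-induced genes, 5 were higher and none lower, with Ier3 followed by the MAP kinase phosphatase Dusp6 (3.02-fold), Gadd45b (2.41-fold) and Egr1 (2.22-fold). That list's median of 0.19 lay at the 98.9th percentile, and at the 93.5th on array 1 alone.

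The medians of the proliferation lists were above 0, while most members were not called. All 17 DNA replication genes had a mean above 0 (median 0.36, 99.8th percentile), and 1 of them, the thymidine kinase Tk1 (2.19-fold), passed 2-fold on both arrays. The origin recognition gene Orc1 stood at 1.14 ± 0.15. Of 23 mitosis genes, 21 had a mean above 0 (median 0.56, above all random lists). Only 16 of the 23 had the same sign on both arrays, at the 90.4th percentile of random lists. Mki67, the proliferation antigen (2.26-fold), and the topoisomerase Top2a (2.22-fold) were called. The checkpoint kinase Bub1 stood at 1.30 ± 0.44. Glycolysis genes had a median of 0.75 over 11 genes (99.99th percentile). Of these, 7 were at least 1.5-fold higher on both arrays and Tpi1, triosephosphate isomerase, was 2.63-fold higher. Oxidative phosphorylation genes had a median of 0.14 with none called (85.7th percentile). Cytosolic ribosomal protein genes lay the other way: 20 of 22 had a mean below 0, the median was -0.55, below all random lists, and Rps4x was 2.10-fold lower. Genes of secretion and the unfolded protein response had a median of 0.35 (99.5th percentile, 97.2nd on array 1 alone and 91.2nd by the mean of members), with none called and Xbp1, a secretory pathway transcription factor, at 0.93 ± 0.10.

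Among chemokines and their receptors, 6 of 17 were higher and none lower (median 0.44, 99.9th percentile; 0.75 on array 1 alone and 0.71 on array 2 alone). The monocyte and T cell chemokine receptor Ccr2 was 10.7-fold higher, Ccl6 7.08-fold, Cxcl2 3.21-fold and Ccl1 2.81-fold. Of 9 granule and killer cell genes, Gzmb and the granule proteoglycan Srgn (2.56-fold) were higher (median 0.49, 99.4th percentile; 0.83 on array 1 alone and 0.38, at the 95.8th percentile, on array 2 alone). Cytokine feedback genes included Cish (6.42-fold), a STAT5 target, Socs3 (2.90-fold) and the kinases Jak3 (2.25-fold) and Jak2 (2.23-fold); the list's median of 0.10 lay at the 84.6th percentile. That median was 0.31 on array 1 alone and 0.33, at the 98.4th percentile, on array 2 alone, and the mean of members was 0.43, at the 98.2nd percentile. Of 22 apoptosis regulators, Casp1 (4.32-fold), the BH3-only gene Pmaip1 (3.98-fold) and Casp4 (2.92-fold) were higher (median 0.03, 64.2nd percentile). Interferon response genes had a median of -0.15 (2.71st percentile), and the interferon-inducible GTPases Iigp1 (2.88-fold) and Tgtp1 (2.10-fold) were lower. The interferon median was -0.28, at the 0.91st percentile, on array 1 alone and -0.06 on array 2 alone, and the mean of members was -0.25, at the 0.46th percentile. Neither cholesterol and fatty acid synthesis (median -0.14, mean 0.02, 14.2nd percentile) nor heat shock genes (median -0.07, 27.5th percentile) held a called gene.

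**Figure D3:**
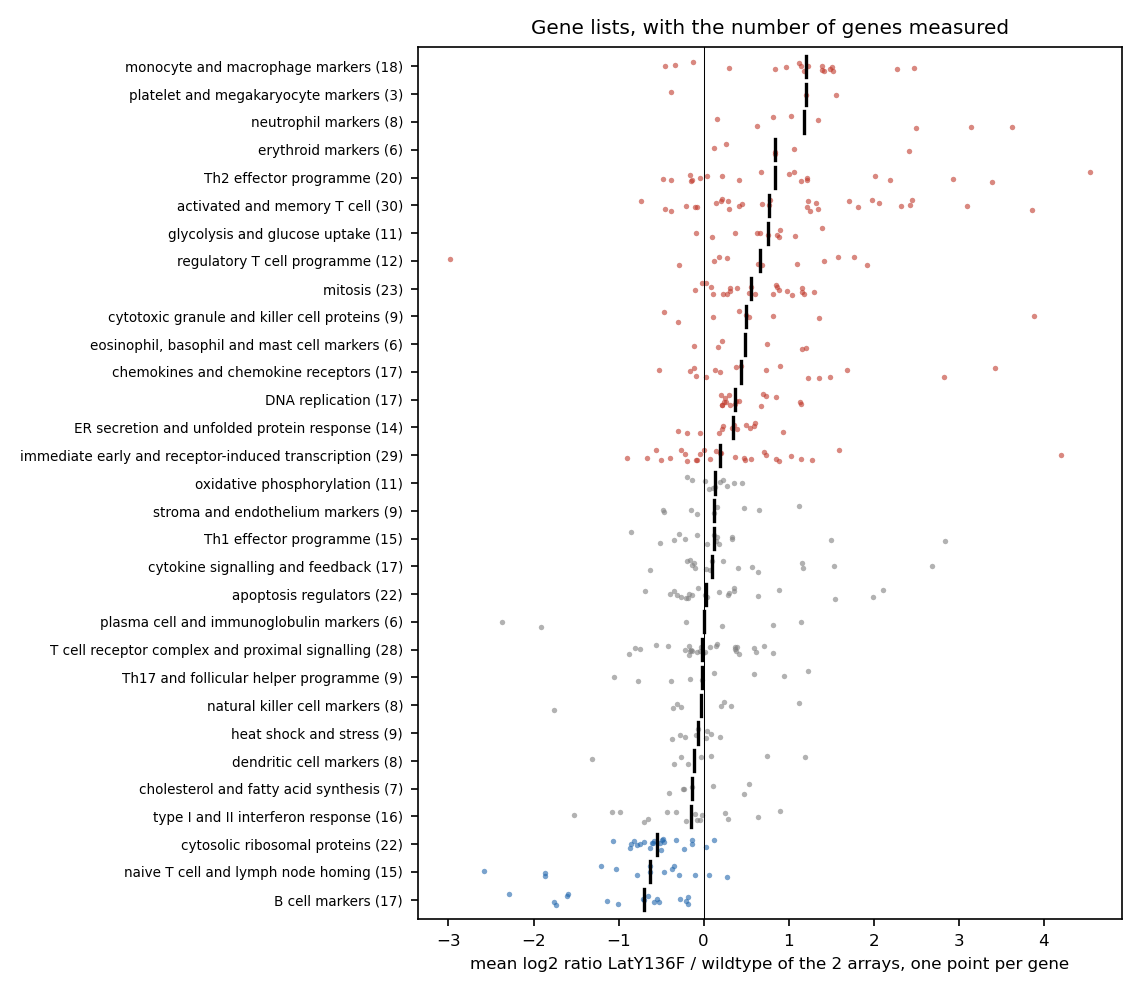
Mean log2 ratio of LatY136F over wildtype of the 2 arrays (x axis) for each measured gene (points) of the 31 lists with at least 3 measured genes (rows, with that number); black bars are medians. Red and blue mark the 15 lists above and the 3 below the central 95% of 10000 random lists. Monocyte and macrophage markers and platelet markers lie highest (1.20 each) and B cell markers lowest (-0.70).

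Markers of other cell types differed beside the groups above. Of 18 monocyte and macrophage markers, 9 were at least 2-fold higher and none lower (median 1.20, above all random lists), led by the complement gene C1qc (5.57-fold), Lyz1 (4.84-fold), Vcam1 (2.88-fold) and Fcer1g (2.83-fold). Neutrophil markers had a median of 1.18 over 8 genes, also above all random lists, with Il1r2, Lcn2 (8.83-fold) and the granule protein Ngp (5.65-fold) called. That median was 2.10 on array 1 alone and 0.84 on array 2 alone. Erythroid markers (6 measured, median 0.84, 99.9th percentile) included the erythropoietin receptor Epor (5.35-fold) and Hba-a1 (2.10-fold). Platelet markers (3 measured, median 1.20, 99.5th percentile, 96.8th by the mean) included Pf4 (2.93-fold) and Itga2b (2.30-fold). The other platelet marker measured had a mean below 0. Eosinophil, basophil and mast cell markers had a median of 0.48 with none called, at the 98.4th percentile, the 91.0th on array 2 alone and the 96.0th by the mean.

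B cell markers were lower: 6 of 17 by at least 2-fold and none higher, with all 17 means below 0 and a median of -0.70, below all random lists. Cd79b was followed by the complement receptor Cr2 (3.38-fold lower), Cd72 (3.33-fold) and the adaptor Blnk (3.05-fold). Immunoglobulin and plasma cell genes went both ways, with Igha and Ighm lower while the joining chain Jchain stood at 1.15 ± 0.26 and Igkc at 0.81 ± 0.10 (median 0.003, mean -0.39, at the 1.29th percentile by the mean). Beside Cd8b1, Cd8a was the only other CD8 T cell marker measured and was not called, at -0.63 ± 0.16. Klrd1, a killer cell receptor, was 3.37-fold lower among natural killer cell markers (8 measured, median -0.03, with -0.15 on array 1 alone and -0.31 on array 2 alone). Dendritic cell markers (8 measured, median -0.11, with -0.14 on array 1 alone and 0.03 on array 2 alone) held Ly6d (2.49-fold lower) and Cst3 (2.28-fold higher). Stromal and endothelial markers (9 measured, median 0.12, with 0.11 on array 1 alone and -0.05 on array 2 alone) held no called gene, with Fn1 at 1.12 ± 0.30. Of the gamma delta T cell markers Sox13 alone was measured, at 1.32 ± 0.21.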

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

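The log2 reading and leaving out probes at exactly 0 were chosen after seeing the data. The 182 higher and 42 lower genes became 177 and 42 without centring, and 188 and 43 with the strongest probe per gene. Scaling the arrays, or leaving out probes at exactly 0, left both counts as they were, and a 2-fold threshold on the mean gave 259 and 59. A threshold of 1.5-fold on both arrays gave 339 higher and 127 lower, and 3-fold gave 69 and 19, as such thresholds must move counts. Single arrays called 341 to 408 genes higher and 145 to 151 lower, since a call then needs 1 array only. Counting all probes singly, unnamed ones included, gave 288 and 84. limma on the 2 arrays as if they were replicates called 0 higher and 0 lower at an adjusted p under 0.05, with 616 genes at an unadjusted p under 0.05; in simulation it recovered no true change either. Turning the sign swaps the counts to 42 higher and 182 lower, and those of shifted lists from 15 above and 3 below to 3 above and 15 below. Read as log2, the table would hold 13 genes at least 2-fold higher and 0 lower, so all folds rest on the log10 reading; the order of genes and lists is fixed under this rescaling. The correlation of the arrays fell from 0.33 over genes to 0.21 over all probes. It reversed to -0.52 among genes with an absolute mean under 0.5, where the limit on the mean itself favours opposite values. Over the alternatives other than the turned sign, the lists above the central 95% of random lists numbered 13 to 15. Those below numbered 3 to 5, 5 where members' means replaced medians; the cause was not tested. Apart from the turned sign, none of 330 alternatives for the 110 genes the rule named reversed a called value. Only 75 of the 110 were called, each with the same sign on both arrays. Either array alone, or scaling, cannot reverse such a gene, so the count says little about robustness. None of 231 alternatives for the lists reversed a called value, while 7 list calls were lost and 5 gained. No paired analysis was possible because both arrays belong to 1 comparison and no other group exists. Matching random lists on signal was not run, as the table holds none.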

Other observations

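All tests of explanations in this part were chosen after the result was seen, as were the gene families that follow. Of 9 prostanoid receptor genes measured, Ptgir, the prostacyclin receptor, was 9.45-fold higher in LatY136F cells (3.24 ± 0.20) and Ptger4, a prostaglandin E receptor, 3.34-fold (1.74 ± 0.20). Tbxa2r, the thromboxane receptor, was 3.27-fold lower (-1.71 ± 0.003), and the other 6 were not called. Of 3 formyl peptide and leukotriene receptor genes, Cysltr1 and, 10.3-fold, Fpr2 were higher, and Ltb4r1 was not called (0.90 ± 0.36). Of 12 annexins, 3 were higher (Anxa1, Anxa2 and, 6.84-fold, Anxa3) and 9 were not called. Of 8 genes grouped from the Pir, Pilr, Lilr and Sirp receptor families, 5 were higher. These were Lilrb4a (5.46-fold), Lilr4b (5.23-fold), Pirb (3.35-fold), Sirpa (2.91-fold) and Pilrb2 (2.78-fold), while Pira1, Pira2 and Pilra were not called. The higher genes are best known from myeloid cells.

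Monocyte and macrophage markers were higher in the LatY136F sample, although selection on CD4 with beads and a sorter would remove most such cells. A lower share of T cells, with the other cells in unchanged proportions, would raise every other cell type alike. The median of these markers exceeded that of B cell markers by 1.90 on the log2 scale. All 17 B cell markers had a mean below 0 (upper quartile -0.52, against a lower quartile of 0.87 for the monocyte and macrophage markers). These values argue against that form only. A lower share of T cells together with fewer B cells was not tested. Medians of neutrophil, erythroid and platelet markers were above 0 too. After turning, 94.4% of the markers had the same sign on both arrays, at the 99.98th percentile of random lists. This does not exclude dye error. The list was singled out for its large mean over both arrays, which favours equal signs, unlike in random lists. The turning of array 2 also rested on the correlation of these same arrays. More monocytes or macrophages in the LatY136F sample may account for the pattern. Of the markers, 72.2% were at least 1.5-fold higher on both arrays, while Itgam (0.29), Ctss (-0.13), Marco (-0.34) and Msr1 (-0.45) were among those that were not. That share restates the pattern and cannot tell more such cells from expression by T cells. No measured gene of this list stands in another list. Expression of such genes by the LatY136F T cells themselves stays open and was not tested.

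B cell markers and Cd8b1 were lower in the LatY136F sample, although selection on CD4 with beads and a sorter would remove most B cells from both samples. After turning, 94.1% of the 17 B cell markers had the same sign on both arrays, which for the same reasons does not exclude dye error. Fewer B cells among the LatY136F cells is a candidate explanation that the values leave undecided, since 47.1% of the markers were at least 1.5-fold lower on both arrays and Cd79a stood at -0.55 beside -2.29 for Cd79b. The table gives ratios without signal, so the share of such cells in either sample cannot be set.

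Rgs10, the lowest gene of all, is one of the measured genes that neighbour Lat in the mouse genome (RefSeq order, GRCm38.p6). Of the 50 measured genes nearest to Lat, 4 were at least 2-fold lower (Tbx6, Rgs10, Prkcb and Rps15a), against 0.49 expected from the share over all genes, and none was higher. As many lower genes were held by 0.53% of windows of 50 around other genes. Such windows overlap, and those around genes near Lat hold many of the same genes. This share and those that follow are therefore not probabilities of chance. Among the nearest 25 and 100 genes, 2 and 5 were lower, counts reached by 2.18% and 2.32% of windows. With Rgs10, which prompted the question, left out of all genes, 3 of the 50 nearest were lower, a count reached by 1.27% of windows of 50 genes around other genes, but the lower direction was also chosen after it was seen. In either direction 24.4% of windows held at least 4, so neither chance position nor DNA of another strain carried along with the edited Lat gene, which might give such a cluster, can be excluded. Prkcb is also expressed by B cells, whose markers were lower, and Rps15a is a ribosomal protein gene, a class that was lower as well.

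Among genes with more than 1 probe (294), the mean log2 ratios of the first 2 probes correlated with a Pearson r of 0.62 (Spearman rho 0.45) across genes, whereas the differences between the arrays did not (r = 0.0001). By the mean of the 2 arrays, a looser rule than the call on each array, 31 such genes had at least 1 of these probes 2-fold apart. Of them, 14 had both 2-fold apart the same way. Over the 3360 probes without a single gene symbol the arrays correlated with r = 0.03, against 0.32 for probes with one, and 89 of the former were at least 2-fold higher and 39 lower on both arrays. The unnamed probes furthest apart had IDs 638949 (22.4-fold higher) and 634392 (16.9-fold higher), and 638351 (9.17-fold lower) and 635757 (9.06-fold lower).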
